A study of Zea mays with 12 samples.

How the data were processed

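Whole endosperms were collected at 16 days after pollination from field-grown, self-pollinated W22 plants, and RNA was extracted and DNase treated. Libraries were made from polyadenylated RNA with a strand-specific Illumina kit, per the labels' protocols. There were 12 samples in 3 genotype groups of 4, which the series design calls biological replicates. Group and replicate number were taken from the labels. FastQC, TopHat2 2.1.1, featureCounts and Cufflinks 2.2.1 are named in the submitters' processing notes, with no role or order. The genome build, the annotation, and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart.

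Each deposited table held 1 value per gene for 34348 genes, and the values are RPKM as deposited by the authors, judged from the values themselves since the file headers name only the sample. Within a gene, values across libraries were whole multiples of 1 step after 1 factor per library, and the steps across genes were inverse whole numbers, as RPKM values give. Whole reads, gene lengths and library factors were recovered from these steps for 34307 of the 34307 genes with a value above 0, with a tolerance of 0.02 reads. Of 500 control genes whose values had been shifted at random by 0.1%, 1 still came out whole. On simulated data the recovery was exact for 99.98% of 5501 genes with at least 10 mean reads. The remaining 41 genes were 0 in every library.

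Recovered reads summed to 35.3 to 48.0 megareads per library. The library factors in the deposited values equalise the bulk of genes rather than the totals: they were 27.3 to 31.1 megareads in WT, 34.3 to 40.5 megareads in the libraries labelled nkd1-Ds and 27.8 to 30.9 megareads in nkd2-Ds. Whether the counted units were reads or fragments is not given in the sources used here. For a gene with 0 reads in all WT libraries, a fold was computed against a floor of 3 reads per library. Such floors cover counting error only.

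The design fixed before the data were examined assumed read counts, with a branch for normalized values. Since the values were RPKM, that branch was used: limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(RPKM + 1), over 26706 genes with a mean of at least 1 RPKM in at least 1 group. All 12 samples entered with genotype as the only factor. The comparisons were nkd1-Ds with WT, nkd2-Ds with WT and nkd2-Ds with nkd1-Ds, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as a call. Fold changes on this scale understate the change of low genes. The same steps were tested on simulated data with 200 changed genes. The data gave far more calls, which moves the unadjusted p that passes, so the simulated shares need not carry over to them. In the simulation of nkd1-Ds with WT (24843 genes tested), 14% of genes changed 1.25-fold were called with the right sign, 50% at 1.5-fold, 95.9% at 2-fold and 100% at 4-fold, and 3.76% of calls fell on unchanged genes. In that of nkd2-Ds with WT (24836 genes tested) the shares were 14.6%, 57.1%, 90% and 100%, with 5.80% of calls on unchanged genes. Of 100 random lists, 5 and 3 had a camera p under 0.05. Genes were simulated independently of each other, so this does not check camera's preset correlation for lists whose genes vary together.

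Libraries of the same group differed by more than sampling noise (chi-square per gene 8.04 to 85.9), so none was treated as a duplicate. Some pairs were closer than others. In WT, replicates 1 and 2 gave 8.04 and replicates 3 and 4 gave 9.38, against 24.1 to 30.5 across these pairs. In nkd2-Ds, replicates 3 and 4 gave 10.6, against 66.5 and 85.9 with replicate 1. All fits treated the 4 libraries of a group as independent, which these values do not settle. Comparisons that share the WT libraries were set beside 100 simulated draws of unchanged groups, the overlap of independent lists, and 6 splits of WT into 2 and 2.

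18 gene lists were fixed before the data were examined: zein storage proteins, endosperm transcription factors, starch synthesis, aleurone, basal transfer layer and embryo-surrounding region, embryo, photosynthesis and pericarp, anthocyanin and flavonoid, carotenoid and plastid isoprenoid, abscisic acid and desiccation, gibberellin and amylases, cell cycle and DNA replication, ER chaperones, heat shock, defence and seed protection, Opaque2 target enzymes, cytosolic ribosomal proteins, and sugar and amino acid transport. Members were matched by symbol or product name. 15 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The minimum of 3 was set after identifiers had been matched. Fry's test asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Genes that shared only an ambiguous alias with a list symbol were left out, judged from their names after identifiers had been matched. With an estimated correlation camera called 0 lists in each comparison, with 2, 3 and 1 lists at an unadjusted p under 0.05, and fry called 11, 8 and 13.

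Gene names came from a RefSeq table of assembly NAM-5.0, used only for names and for gene order. It matched 15235 identifiers, 462 of them to more than 1 gene, and 2035 had an informative name. Named genes followed a rule fixed beforehand: nkd1 and nkd2, then per comparison with WT the 12 genes per direction with the largest change among called, non-overlapping and named genes with at least 5 RPKM in 1 group, 5 per direction for the direct comparison, and up to 3 called members per list, or 2 uncalled where none was called. For the overlap of both comparisons the rule asked for no name, and 0 of the 10 genes it took had one. The 5 per direction with an informative name were used in their place. Members of a list named beyond this rule, as well as c1, betl9 and mn1, were chosen after their values were seen.

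The alternatives planned beforehand were quantile normalization, no filter on low values, a value of 0.1 in place of 1 added before the logarithm, only the 8 samples compared, the replicate number as a block, leaving out each replicate, and lists without shared or multigene members. Scaling by total recovered reads and limma voom on recovered reads were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the tables and figures. Zein copies share reads, so values of single copies are uncertain.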

Results

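RNA was sequenced from whole maize endosperm, the starch-storing and protein-storing tissue of the kernel, at 16 days after pollination. The plants were field grown, self-pollinated and of the W22 inbred background. 3 genotypes were compared, with 4 libraries each that the series describes as biological replicates: wild type (WT), nkd1-Ds and nkd2-Ds. The mutants are named for insertions of the maize transposon Ds. The duplicate genes nkd1 and nkd2 (naked endosperm) code for zinc finger transcription factors of the INDETERMINATE domain family that act in aleurone formation and endosperm maturation. The aleurone is the outer cell layer of the endosperm.

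The libraries held 35.3 to 48.0 megareads assigned to genes. Zein genes, which code for the storage prolamins of the starchy endosperm, took 45.0% ± 3.19 of the reads in WT, 28.3% ± 0.785 in nkd1-Ds and 42.2% ± 5.78 in nkd2-Ds (mean ± SD, n = 4). The nkd2-Ds libraries were spread widely in this share, at 49.7%, 43.6%, 38.6% and 36.8% in replicates 1 to 4. Expression is given as RPKM (reads per kilobase of gene length, relative to library size) on the authors' scale, as mean ± SD of 4 libraries. Changes are differences of log2(RPKM + 1) ± SE, a scale that understates the change of low genes. The principal component that took 54.6% of the variance placed WT at -54.9 to -48.4, nkd2-Ds at -5.33 to 4.72 and nkd1-Ds at 50.3 to 54.7. A gene is called where its Benjamini-Hochberg adjusted p from limma was under 0.05 among 26706 genes tested.

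The targeted genes were compared before all others. nkd1 (GRMZM2G129261) stood at 49.2 ± 3.41 RPKM in WT, 12.8 ± 1.08 in nkd1-Ds and 35.1 ± 1.57 in nkd2-Ds. It fell by 1.87 ± 0.0684 on the log2 scale in nkd1-Ds (limma adjusted p = 2.31e-10) and by less in nkd2-Ds, where it fell by 0.47 ± 0.0684 (adjusted p = 0.000217). The call in nkd2-Ds was lost when libraries were scaled by total reads (adjusted p = 0.0848). nkd2 (GRMZM5G884137) stood at 19.5 ± 0.762 RPKM in WT, 1.14 ± 0.141 in nkd2-Ds and 1.10 ± 0.0780 in nkd1-Ds. It fell by 3.26 ± 0.0696 in nkd2-Ds (adjusted p = 1.34e-12) and fell by 3.29 ± 0.0696 in nkd1-Ds (adjusted p = 9.55e-13). The direct difference of nkd2 between the mutants was 0.03 ± 0.0696 (adjusted p = 0.787). Each of the 4 libraries labelled nkd1-Ds had nkd2 between 1.01 and 1.19 RPKM, within the range of 0.975 to 1.27 RPKM in nkd2-Ds. Of the targeted pair, nkd1 separated the mutant groups and nkd2 did not. Because nkd2 transcript was low in them too, the nkd1-Ds libraries are called the libraries labelled nkd1-Ds, and every direction drawn from them holds for libraries low in both transcripts.

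**Figure D1:**
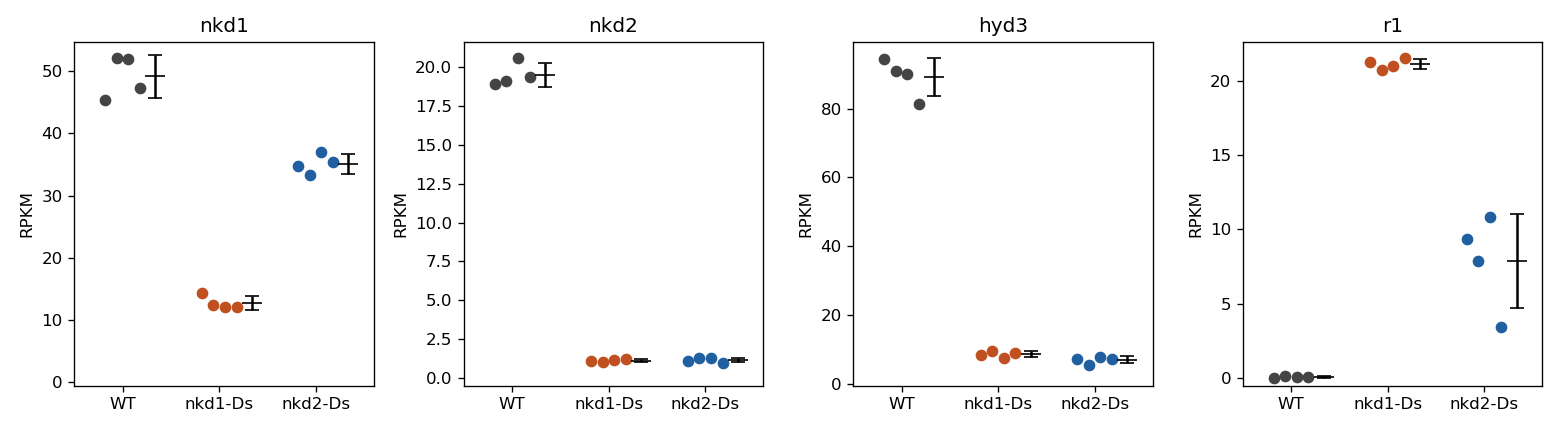
RPKM of nkd1, nkd2, hyd3 and r1 in each library (points), with the mean and SD of the 4 libraries of each genotype (bars to the right of the points); each panel has its own axis. nkd2 is near 1 RPKM in all libraries of both mutant groups, against 19.5 RPKM in WT, while nkd1 is 12.8 RPKM in the libraries labelled nkd1-Ds and 35.1 RPKM in nkd2-Ds.

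The comparison of the libraries labelled nkd1-Ds with WT asks which transcripts changed in that mutant. Of 29 zein storage protein genes 24 were lower on the authors' scale. Quantile normalization, which evens out the highest values between libraries, called 11 of the 29 genes lower and 4 higher. Of the heat shock genes 11 of 14 were higher, as were 3 of 3 endoplasmic reticulum (ER) chaperone genes. With an estimated correlation these lists did not pass, at adjusted p = 0.593 for zeins, adjusted p = 0.343 for heat shock genes and adjusted p = 0.325 for ER chaperones. The sucrose synthase genes sus1, sus2 and sh1 were lower on the authors' scale. hyd3, a beta-carotene hydroxylase gene of the carotenoid pathway, was 89.2 ± 5.56 RPKM in WT and 8.63 ± 0.806 RPKM in these libraries. r1, a bHLH regulator of anthocyanin pigment genes, was 0.0690 ± 0.0484 RPKM in WT and 21.1 ± 0.328 RPKM in these libraries. hsp82, a heat shock protein gene, was 1.57 ± 0.909 RPKM in WT and 108.8 ± 8.02 RPKM in these libraries.

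limma called 14877 of the 26706 genes (55.7%), of which 7077 were higher and 7800 lower than in WT. At least a 2-fold change was found for 2281 called genes, 1187 higher and 1094 lower. The 4 values of each group did not overlap for 13644 genes (51.1%), where chance gives 2.86%. The split into higher and lower calls rests on the scaling: with libraries scaled by total reads, 18637 genes were called, 89.2% of them higher against 47.6% on the authors' scale, and the median of all genes moved from -0.02 to 0.43. In that setting, list medians are given relative to that shift, and list counts cover the members tested on the authors' scale. Those counts and the values of single genes are not corrected for the shift, here and in the other comparisons. Of 27026 genes tested in that setting, 16621 were called higher and 2016 lower. There a lower zein share of reads raises all other genes by construction, so a turned list count alone gives no direction of the list.

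Of 14 heat shock genes 11 rose and 1, hsp70-4, fell (log2 -0.48), against 13 higher and 0 lower with total-reads scaling, with a median of 1.48 (camera adjusted p = 0.00014). With an estimated correlation the adjusted p = 0.343. Adjusted over the list alone, 12 members were called. hsp82 rose by 5.48 ± 0.316 (limma adjusted p = 1.81e-08), hsp22 by 3.94 ± 0.392, HSP90-1 by 3.56 ± 0.243 and hsp101 by 3.48 ± 0.327. A Hsp70 gene (GRMZM2G310431) rose from 154.5 ± 23.9 to 479.5 ± 32.4 RPKM. Outside this list Hsf26, a heat shock transcription factor gene, rose from 0.563 ± 0.0455 to 12.2 ± 1.41 RPKM. The ER chaperone genes crt2 (calreticulin), bip1 and bip2 (binding proteins) also rose, 3 of 3 members, by 1.24, 0.67 and 0.75 (camera adjusted p = 0.00851). For this list the adjusted p = 0.325 with an estimated correlation, and 3 members were called when adjusted over the list alone. With total-reads scaling the median of the heat shock list relative to all genes was 1.59 and that of the ER chaperones 0.86.

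Among 29 zein genes 24 fell and 0 rose on the authors' scale, with a median of -0.85 (camera adjusted p = 0.000118), while total-reads scaling left 13 lower and 1 higher and quantile normalization, which turned some directions, 11 lower and 4 higher with a median of -0.19. Quantile normalization gives every library the same set of values. Zeins hold many of the highest, so a fall shared by them is reduced by construction. As a share of reads, which needs no such scaling, zeins took 42.1% to 48.3% in WT and 27.3% to 29.1% in these libraries. The list's adjusted p = 0.593 with an estimated correlation and 0.232 with quantile normalization, and 26 members were called when adjusted over the list alone. Without alpha zeins and members shared with other lists it was 0.374. That setting leaves at most 5 of the 29 genes, so it says little about the list. The z1A family of alpha zeins fell in 9 of 9 members (median -1.64), z1B in 2 of 3, z1C in 9 of 12 (median -0.81), and the beta, gamma and delta zeins in 4 of 5. z1A2_3 fell from 18028 ± 2779 to 5643 ± 576 RPKM, z1A2_1 from 21601 ± 3404 to 7364 ± 841 RPKM, and z1A2_2 by 1.64 ± 0.205 on the log2 scale (limma adjusted p = 2.01e-05). zp27, a gamma zein, was 17881 ± 472 RPKM in WT and 19133 ± 1923 RPKM in these libraries (log2 0.09 ± 0.215, adjusted p = 0.737). Alpha zein copies are nearly identical and share reads, so the value of any single copy is uncertain.

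For starch synthesis, 11 of 18 members fell and 3 rose on the authors' scale, with a median of -0.33, but with total-reads scaling 3 were lower and 8 higher. The list did not pass the test (camera adjusted p = 0.0626), except without WT replicate 1 (0.0470) and with limma voom on reads (0.0398), and the count adjusted over the list alone was 14. sus2 and sus1, which code for sucrose synthases, changed by -1.97 ± 0.122 (limma adjusted p = 3.66e-08) and -1.49 ± 0.200. wx1, the granule-bound starch synthase gene, fell from 3189 ± 108 to 2146 ± 147 RPKM (adjusted p = 0.000285), a call that was lost with quantile normalization (0.474) and total-reads scaling (0.857). The Opaque2 target list, named for the bZIP activator Opaque2, had 3 of 7 members lower and 0 higher, against 2 lower and 4 higher with total-reads scaling (camera adjusted p = 0.352; 3 adjusted over the list alone). rip1 (GRMZM2G063536), the b-32 ribosome-inactivating protein gene, fell by 0.95 ± 0.134 and zp15 by 1.03 ± 0.230. ppdk2, a pyruvate phosphate dikinase gene, fell by 0.51 ± 0.107, but was 0.0521 with quantile normalization and 0.0415 with total-reads scaling.

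The carotenoid list had 5 of 6 members lower and 0 higher (median -0.42, camera adjusted p = 0.0215), against 2 lower and 1 higher with total-reads scaling. Its adjusted p = 0.325 with an estimated correlation, and 5 members were called when adjusted over the list alone. hyd3 fell by 3.23 ± 0.0946 (limma adjusted p = 2.19e-11) and y1, the phytoene synthase gene, by 1.14 ± 0.0912, while pds1 (GRMZM5G815358), the phytoene desaturase gene, fell by 0.40 ± 0.0961 but was 0.10 with total-reads scaling. Among the aleurone genes 6 of 12 fell, nkd1 and nkd2 being among them, and 2 rose (camera adjusted p = 0.113; 8 adjusted over the list alone), against 4 and 4 with total-reads scaling, where the list passed the test (0.00631). ole17, an oleosin gene of oil bodies, fell from 31.7 ± 1.57 to 5.30 ± 1.15 RPKM, and r1 rose by 4.37 ± 0.221 (limma adjusted p = 5.33e-09). In gene order r1 lies 8 and hyd3 10 placed genes from nkd2 (RefSeq table of assembly NAM-5.0). Only 12141 of the tested genes could be placed, so unplaced tested genes may lie between.

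Anthocyanin and flavonoid genes went both ways in the libraries labelled nkd1-Ds. Of 11 members 2 rose and 3 fell, against 4 higher and 0 lower with total-reads scaling. The median was -0.16, whereas the mean was 0.35 and the test pointed up (camera adjusted p = 0.845; 4 adjusted over the list alone). bz1 (GRMZM2G165390) rose from 0.115 ± 0.0518 to 1.84 ± 0.360 RPKM, while a2 (GRMZM6G474234) fell by 0.75 ± 0.0790, a call lost with total-reads scaling (adjusted p = 0.0657). Of 4 gibberellin and amylase genes 3 rose and 1 fell (median 0.79, camera adjusted p = 0.153; 4 adjusted over the list alone). amy2, an amylase gene, rose from 0.0440 ± 0.0171 to 15.5 ± 1.62 RPKM, and the DELLA repressor genes d8 and d9 rose by 0.93 ± 0.129 and 0.66 ± 0.101. an1, which codes for ent-copalyl diphosphate synthase of gibberellin synthesis, fell by 1.64 ± 0.111.

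The remaining lists went in mixed directions. For abscisic acid and desiccation 3 of 7 members rose and 2 fell, against 4 and 1 with total-reads scaling (camera adjusted p = 0.707; 6 adjusted over the list alone), with dehydrin7 rising by 1.52, rab15 by 0.33 and aba1 (asr1) falling by 1.57. For the cell cycle 4 of 18 rose and 5 fell (camera adjusted p = 0.613, with 9 called when adjusted over the list alone). With total-reads scaling, where most of all tested genes were called higher, 13 members were higher and 0 lower. On the authors' scale cdc2 rose by 1.60 and cyclin9 by 0.40, while rbr3 fell by 0.35 but was 0.0164 with total-reads scaling. For defence and seed protection 5 of 11 rose and 4 fell, against 6 higher and 1 lower with total-reads scaling (camera adjusted p = 0.556; 9 adjusted over the list alone), with lox3 rising by 1.55, pal1 by 1.05 and lox1 by 0.82. Of 13 endosperm transcription factor genes 4 rose and 4 fell, the latter being nkd1, nkd2, vp1 and pbf1, against 7 and 3 with total-reads scaling (camera adjusted p = 0.585; 8 adjusted over the list alone). pbf1 (GRMZM2G146283), the prolamin-box binding factor gene, fell from 103.3 ± 7.43 to 53.5 ± 4.95 RPKM. Of 3 transport genes sut2 rose by 0.37 and sut4 fell by 0.26, which was 0.19 with total-reads scaling (camera adjusted p = 0.613; 2 adjusted over the list alone). The cell cycle list had 9 members and the defence list 2 members that did not pass.

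Markers of other cell types were measured as lists too. Of 14 genes of the basal transfer layer and embryo-surrounding region limma called 0 (2 at an unadjusted p under 0.05, 0 with voom), with camera adjusted p = 0.613 and 0 adjusted over the list alone, although with total-reads scaling the list passed (0.00982). With only the 8 samples compared in the fit, bap1a (limma adjusted p = 0.0476) and bap1b (0.00944) were called, as was bap1b with total-reads scaling (0.0157). bap1a was 4.98 ± 2.82 RPKM in WT and 1.82 ± 0.742 RPKM here, and bap1b 2.87 ± 1.67 and 8.44 ± 3.49 RPKM. Of the embryo genes tested lg3, a knotted-like homeobox gene, rose by 1.12 and wox2a was -0.05 (adjusted p = 0.674; 1 of 2 adjusted over the list alone). Of 2 photosynthesis genes psah1 rose by 0.77 and psad1 fell by 0.45 (2 adjusted over the list alone), both near 1 RPKM or lower. The list of cytosolic ribosomal proteins matched 0 genes.

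The largest rises by the rule for named genes included kin1, which had 0 reads in all WT libraries and 37.5 ± 6.59 RPKM in the libraries labelled nkd1-Ds, at least 549-fold higher against a floor of 3 reads per WT library. ERTC rose from 2.76 ± 0.6595 to 60.4 ± 3.49 RPKM, TMT from 0.493 ± 0.276 to 18.4 ± 1.87, BURP4 from 0.173 ± 0.204 to 9.37 ± 2.31 and GH3 from 3.27 ± 4.35 to 25.04 ± 3.07. Among the largest falls were TIP3-1, a tonoplast aquaporin gene, from 86.3 ± 21.8 to 15.7 ± 6.34 RPKM, and gln2, a glutamine synthetase gene, from 68.5 ± 7.87 to 13.4 ± 2.96 RPKM. SnRK2.5, a protein kinase gene, fell by 2.13 ± 0.0733, HO1 by 2.17 ± 0.132, a PDIL5-1 gene (GRMZM2G443655) fell by 2.12 ± 0.152 and ICL, the isocitrate lyase gene, by 1.77 ± 0.190. For each gene taken by this rule all 4 mutant libraries lay on one side of all 4 WT libraries.

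The comparison of nkd2-Ds with WT asks which transcripts changed in the other mutant. Of 11 anthocyanin and flavonoid genes 8 rose and 0 fell, in a list that did not pass with an estimated correlation (adjusted p = 0.189). bz2, a glutathione transferase gene of pigment transport, was 0.798 ± 0.240 RPKM in WT and 15.8 ± 5.19 RPKM in nkd2-Ds, and a1, the dihydroflavonol reductase gene, 0.239 ± 0.166 and 10.3 ± 3.89 RPKM. r1 rose to 7.87 ± 3.18 RPKM. hyd3 was lower, at 6.96 ± 1.03 RPKM. glb1, a globulin storage protein gene of embryo and aleurone, rose from 6.02 ± 1.28 to 34.7 ± 13.2 RPKM.

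limma called 6823 of 26706 genes (25.5%), of which 3199 were higher and 3624 lower. At least a 2-fold change was found for 1014 called genes, 586 higher and 428 lower. Groups did not overlap for 7041 genes (26.4%, against 2.86% by chance). With total-reads scaling 4524 genes were called, 72.4% of them higher against 46.9% on the authors' scale, and the median of all genes moved from -0.01 to 0.12.

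Anthocyanin and flavonoid genes rose in 8 of 11 members and fell in 0, with a median of 1.996 (camera adjusted p = 1.04e-06), and 8 rose and 0 fell with total-reads scaling too. With an estimated correlation the adjusted p = 0.189, and 8 members were called when adjusted over the list alone. With total-reads scaling the median was 1.85, or 1.18 with another member that passed the filter only there, and it was 4.29 with voom, which does not add 1 RPKM before the logarithm. bz2 rose by 3.18 ± 0.187 (limma adjusted p = 3.75e-08), a1 by 3.14 ± 0.193 and fht1, the flavanone hydroxylase gene, by 2.37 ± 0.150. c1, a MYB activator of the same enzymes named after its values were seen, rose by 0.45 ± 0.117 (adjusted p = 0.0130). Aleurone genes rose in 6 of 12 members and fell in 2, those being nkd2 and nkd1 (camera adjusted p = 0.112; 9 adjusted over the list alone), and the list passed without nkd2-Ds replicate 1 (0.0214) and without members shared with other lists (0.0105). glb1 rose by 2.29 ± 0.216 and r1 by 2.96 ± 0.221. ole17 rose by 1.02 ± 0.215 and ICL by 1.03 ± 0.190, where both fell in the libraries labelled nkd1-Ds.

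**Figure D2:**
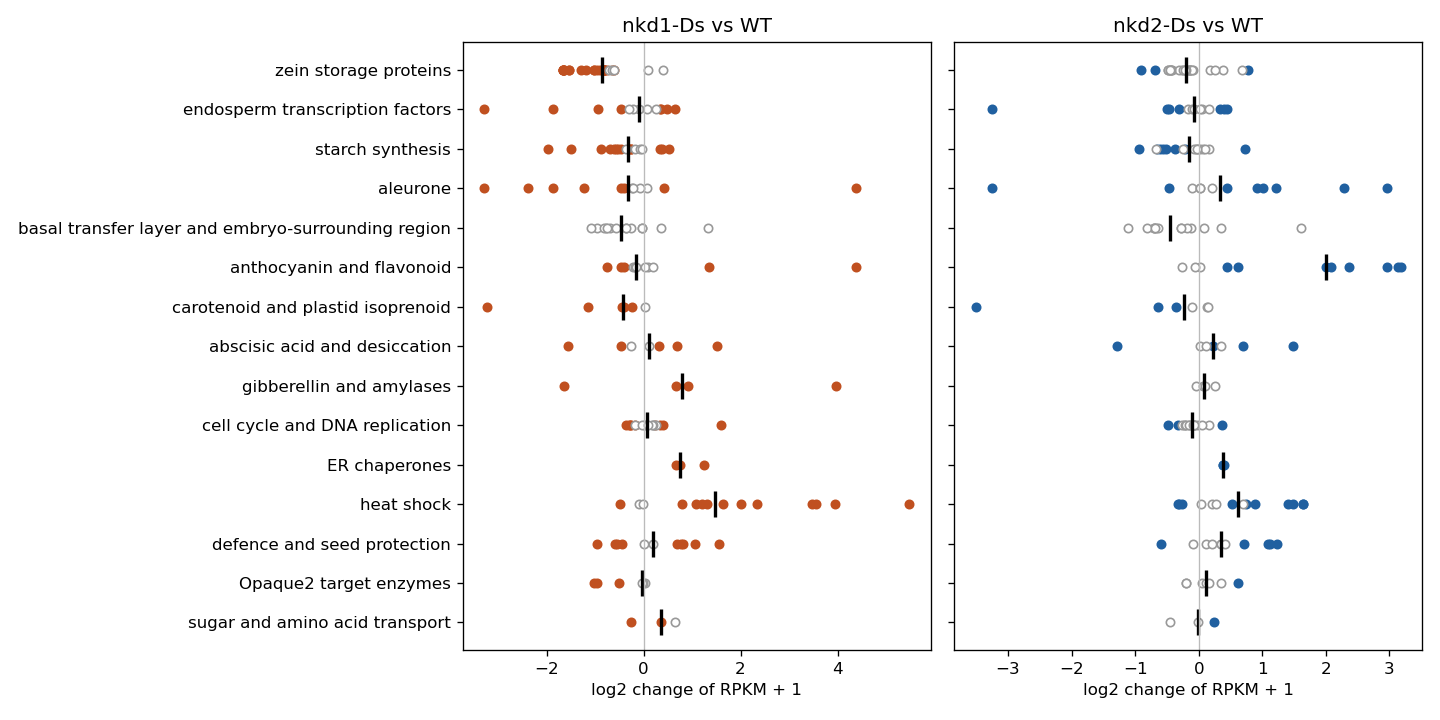
Change of each tested member of 15 gene lists against WT, as the difference of log2(RPKM + 1), for the libraries labelled nkd1-Ds and for nkd2-Ds; filled points passed limma's threshold, open points did not, and the black tick is the list median. Heat shock members lie mostly to the right in nkd1-Ds (median 1.48), anthocyanin members in nkd2-Ds (median 1.996), and zein members lie to the left in nkd1-Ds on the authors' scale (median -0.85). With quantile normalization, which evens out the highest values between libraries, 11 zein members are called lower and 4 higher in nkd1-Ds.

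Heat shock genes rose in 7 of 14 members and fell in 3 (median 0.61, camera adjusted p = 0.0441), against 7 and 0 with total-reads scaling and 9 and 0 with quantile normalization. The list's adjusted p = 0.517 with an estimated correlation, and 11 members were called when adjusted over the list alone. The call was lost with total-reads scaling (0.0567), with the replicate number as a block (0.0525), and without any of WT replicates 1, 3 and 4 or nkd2-Ds replicates 3 and 4 (0.0536 to 0.108). The nkd2-Ds libraries were uneven in this list, with means of log2(RPKM + 1) of 5.05 and 4.96 in replicates 1 and 2, near the highest WT library at 4.92, and of 5.86 and 5.61 in replicates 3 and 4. hsp82 was 4.43, 3.53, 13.04 and 9.08 RPKM in replicates 1 to 4, and hsp101 24.8, 22.7, 84.2 and 61.4 RPKM. hsp82 rose to a mean of 7.52 ± 4.41 RPKM, HSP90-1 by 1.64 ± 0.243 (limma adjusted p = 0.000258) and hsp101 by 1.48 ± 0.327. hsp22 rose by 1.40 ± 0.392 (adjusted p = 0.0189), a call lost without WT replicate 3 or 4 or nkd2-Ds replicate 3 or 4 (0.0520 to 0.0569). The ER chaperone genes crt2, bip1 and bip2 rose by 0.38, 0.39 and 0.38, 3 of 3 members (camera adjusted p = 0.0139; adjusted p = 0.194 with an estimated correlation; 3 adjusted over the list alone). Defence and seed protection genes rose in 4 of 11 members and fell in 1 (camera adjusted p = 0.0137; adjusted p = 0.194 with an estimated correlation; 7 adjusted over the list alone). prp2, a pathogenesis-related protein gene, rose from 99.5 ± 2.199 to 216.2 ± 40.5 RPKM, rip2 by 1.12 ± 0.131 and pal1, the phenylalanine ammonia-lyase gene, by 0.71 ± 0.0897.

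The carotenoid list had 3 of 6 members lower and 0 higher (median -0.23, camera adjusted p = 0.0441; adjusted p = 0.194 with an estimated correlation; 3 adjusted over the list alone). Its call was lost without WT replicate 1 or 2 or nkd2-Ds replicate 1 or 4 (0.0546 to 0.0847) and with the replicate number as a block (0.0525). hyd3 fell by 3.51 ± 0.0946 (limma adjusted p = 1.21e-11), y1 by 0.64 ± 0.0912 and pds1 (GRMZM5G815358) by 0.36 ± 0.0961, the last a call lost with total-reads scaling (adjusted p = 0.208). BCH1, another beta-carotene hydroxylase gene, fell from 5.73 ± 0.442 to 1.77 ± 0.635 RPKM. It was as low in the libraries labelled nkd1-Ds, at 1.78 ± 0.249 RPKM.

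Among 29 zein genes 2 fell and 1 rose (median -0.21, camera adjusted p = 0.222; 3 adjusted over the list alone), against 2 and 2 with total-reads scaling. The list passed without nkd2-Ds replicate 1 (0.00951) and with total-reads scaling (0.0142). dzs18, a delta zein gene, fell by 0.91 ± 0.232 and z1A1_8 by 0.69 ± 0.189, the last lost without WT replicate 3 or 4 or nkd2-Ds replicate 3 or 4 (0.0511 to 0.0526). zp27 rose to 30940 ± 6037 RPKM (adjusted p = 0.0183), a call lost without a filter on low values (0.169), with the replicate number as a block (0.0612) and without WT replicate 3 (0.0510). Starch synthesis genes fell in 7 of 18 members and rose in 1, sus2, against 3 lower and 1 higher with total-reads scaling and 4 lower and 2 higher with quantile normalization (median -0.15, camera adjusted p = 0.119; 8 adjusted over the list alone). sh1, a sucrose synthase gene, fell from 3299 ± 367 to 1724 ± 189 RPKM, agpsl1 fell by 0.56 ± 0.0959, and sus2 rose by 0.73 ± 0.122. In the libraries labelled nkd1-Ds sh1 was lower too, at 2047 ± 224 RPKM, and agpsl1 fell by 0.46, while sus2 fell by 1.97.

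For abscisic acid and desiccation 3 of 7 members rose and 1 fell in nkd2-Ds, against 4 and 1 with total-reads scaling (camera adjusted p = 0.134; 5 adjusted over the list alone), with rab17 (dhn1), a dehydrin gene, rising from 0.600 ± 0.238 to 3.44 ± 0.319 RPKM, dhn2 rising by 0.70 and aba1 falling by 1.29. For the cell cycle cdc2 rose by 0.37, and pcna1 and rbr3 fell by 0.49 and 0.33, both lost with total-reads scaling, which left 1 higher and 0 lower of the list (camera adjusted p = 0.222; 3 adjusted over the list alone). Of 13 endosperm transcription factor genes 3 rose and 4 fell, the latter being nkd1, nkd2, dof36 and pbf1, against 3 and 2 with total-reads scaling (camera adjusted p = 0.256; 9 adjusted over the list alone), and pbf1 (GRMZM2G146283) fell by 0.50 ± 0.0820. Of 7 Opaque2 targets lkrsdh1, a lysine degradation gene, rose by 0.62 (camera adjusted p = 0.355; 1 adjusted over the list alone). Of 3 transport genes sut2 rose by 0.23 (1 adjusted over the list alone), with a list median of -0.01 and a mean of -0.08 while the test pointed up (camera adjusted p = 0.627). Of 4 gibberellin and amylase genes limma called 0 (1 at an unadjusted p under 0.05, 0 with voom), with d9 at 0.25 and d8 at 0.10 (camera adjusted p = 0.503; 0 adjusted over the list alone).

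Genes of the basal transfer layer and embryo-surrounding region gave 0 of 14 calls with limma (2 at an unadjusted p under 0.05, 0 with voom; camera adjusted p = 0.503; 0 adjusted over the list alone), and their mean log2 level ranged from 1.60 to 4.78 among the nkd2-Ds libraries and from 2.57 to 4.49 in WT. bap1b was 13.7 ± 10.7 RPKM and bap1a 1.69 ± 1.20 RPKM. The embryo genes lg3 and wox2a were 0.26 and -0.08 against WT (adjusted p = 0.3005 and 0.591; 0 adjusted over the list alone), with 0 called by limma, 0 by voom and 0 at an unadjusted p under 0.05. psah1 rose by 0.36 and psad1 was -0.11 (1 adjusted over the list alone), the call of psah1 being lost with quantile normalization (0.0590) and without nkd2-Ds replicate 2 (0.0516).

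Further genes taken by the rule for the largest changes rose from 46.1 ± 7.52 to 140.7 ± 43.7 RPKM for plt1, named for a phospholipid transfer protein, from 2.76 ± 0.6595 to 9.50 ± 5.14 for ERTC, from 4.10 ± 1.35 to 11.3 ± 2.33 for sip1 and from 7.70 ± 0.622 to 20.8 ± 5.45 for HMT-4. Lower genes included PDIL5-1, whose copies GRMZM2G443655 and GRMZM2G073628 fell by 2.22 ± 0.152 and 1.04 ± 0.0767. HO1 fell by 1.91 ± 0.132, RAB2B, a small GTPase gene, by 1.20 ± 0.116, PPR-814a, a pentatricopeptide repeat gene, by 1.12 ± 0.0975, COR413-TM1 by 1.07 ± 0.0905 and cc10, a cystatin gene, by 0.86 ± 0.137. GRMZM2G168651 (HRGP) fell by 1.53 ± 0.519 (limma adjusted p = 0.0454), a call lost without WT replicate 1 or 4 or nkd2-Ds replicate 1, 3 or 4, without a filter on low values, with voom and with total-reads scaling (adjusted p 0.0548 to 0.128).

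The direct comparison of nkd2-Ds with the libraries labelled nkd1-Ds tests whether the mutants differ. In nkd2-Ds 11 of 14 heat shock genes were lower, and 7 of 12 aleurone genes were higher and 1 lower. Of 11 anthocyanin genes 7 were higher and 3 lower. Of 29 zein genes 18 were higher on the authors' scale, against 10 higher and 3 lower under quantile normalization. With an estimated correlation none of these 4 lists passed, with adjusted p = 0.257 for heat shock, aleurone and anthocyanin genes and adjusted p = 0.557 for zeins. hsp82 was 7.52 ± 4.41 RPKM in nkd2-Ds and 108.8 ± 8.02 RPKM in the libraries labelled nkd1-Ds. bz2 was 15.8 ± 5.19 and 0.291 ± 0.0988 RPKM, and ole17 68.6 ± 24.7 and 5.30 ± 1.15 RPKM.

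limma called 11157 of 26706 genes, 5759 higher and 5398 lower in nkd2-Ds, of which 1076 differed at least 2-fold (467 higher and 609 lower). Groups did not overlap for 10116 genes (37.9%, against 2.86% by chance). With total-reads scaling 14144 were called, 10.1% of them higher against 51.6% on the authors' scale, and the median of all genes moved from 0.02 to -0.30.

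The heat shock list was lower in 11 of 14 members and higher in 0 (median -1.08, camera adjusted p = 1.48e-05; adjusted p = 0.257 with an estimated correlation; 13 adjusted over the list alone). ER chaperones were lower in 3 of 3 members (camera adjusted p = 0.0158; adjusted p = 0.257 with an estimated correlation; 3 adjusted over the list alone). Zein genes were higher in 18 of 29 members and lower in 0, against 10 higher and 3 lower with quantile normalization (camera adjusted p = 2.59e-05; adjusted p = 0.557 with an estimated correlation; 20 adjusted over the list alone). The zein call was lost with quantile normalization (0.135), which evens out the highest values between libraries. It was also lost without alpha zeins and members shared with other lists (0.172), which leaves at most 5 of the 29 members. Aleurone genes were higher in 7 of 12 members and lower in 1, r1 (camera adjusted p = 0.00734; adjusted p = 0.257 with an estimated correlation; 10 adjusted over the list alone), against 6 and 4 with total-reads scaling. Anthocyanin genes were higher in 7 of 11 members and lower in 3, namely r1, bz1 (GRMZM2G165390) and chi1, against 7 and 4 with total-reads scaling (camera adjusted p = 0.00734; adjusted p = 0.257 with an estimated correlation; 10 adjusted over the list alone). Opaque2 targets were higher in 4 of 7 members (camera adjusted p = 0.0407; adjusted p = 0.257 with an estimated correlation; 4 adjusted over the list alone), a call lost with quantile normalization (0.135), without shared members (0.244), without nkd1-Ds replicate 3 (0.0704) and without nkd2-Ds replicate 2 (0.0591).

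**Figure D3:**
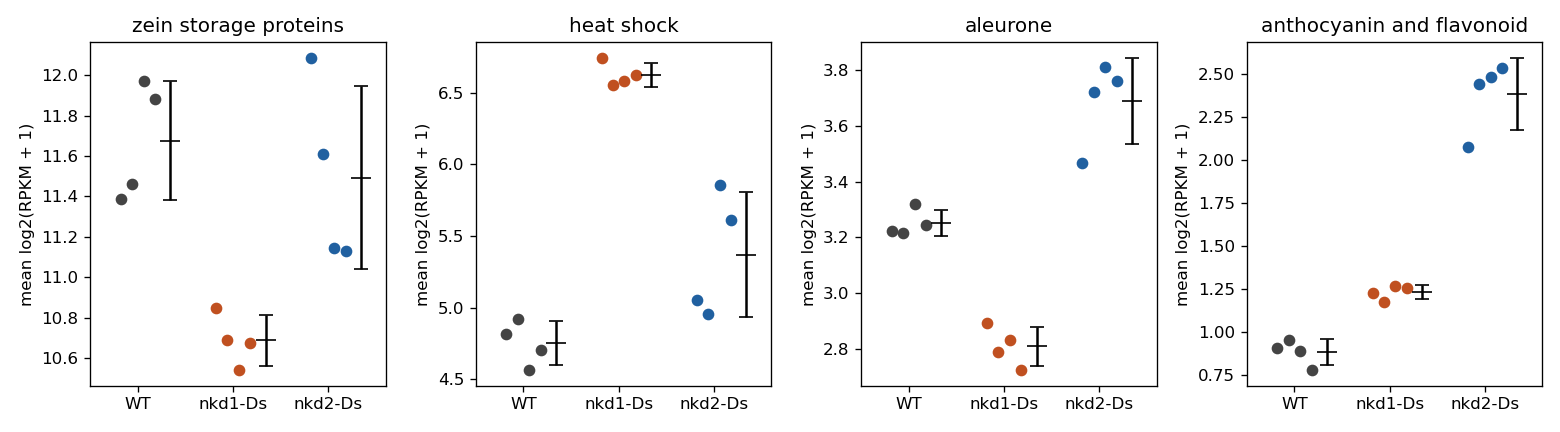
Mean log2(RPKM + 1) over the tested members of the zein, heat shock, aleurone and anthocyanin lists in each library (points), with the mean and SD of the 4 libraries of each genotype (bars to the right of the points); the axes do not start at 0. Heat shock means of the libraries labelled nkd1-Ds are 6.56 to 6.74, above the WT range of 4.56 to 4.92, and anthocyanin means of nkd2-Ds are 2.07 to 2.53, above all other libraries. The zein means, 10.54 to 10.85 in nkd1-Ds and 11.39 to 11.97 in WT, hold on the authors' scale. Quantile normalization, which evens out the highest values between libraries, calls 11 zein genes lower and 4 higher in nkd1-Ds.

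The other lists were not called in the direct comparison. Their camera adjusted p values were 0.724 for endosperm transcription factors (4 higher and 3 lower, against 2 and 7 with total-reads scaling, with a median of -0.02 against a mean of 0.11 and an upward test), 0.654 for starch synthesis (5 and 3, against 2 and 9 with total-reads scaling) and 0.0839 for the cell cycle (1 and 8), which passed without nkd2-Ds replicate 4 (0.0222). They were 0.925 for the basal transfer layer (0 called by limma, 0 by voom and 0 at an unadjusted p under 0.05), 0.362 for carotenoids (2 and 1, against 0 and 2 with total-reads scaling), 0.654 for abscisic acid (2 and 1, against 1 and 3), 0.117 for gibberellin and amylases (1 and 3), 0.654 for defence (4 and 3, against 3 and 4) and 0.689 for transport (1 and 1, against 0 and 2). The embryo gene lg3 differed by -0.86, and of the photosynthesis genes psad1 differed by 0.34 and psah1 by -0.41. By the rule for named genes the largest differences upward were bz2 (3.65 ± 0.187), ole17 (3.41 ± 0.215), a1 (3.37 ± 0.193), ICL (2.80 ± 0.190) and sus2 (2.70 ± 0.122). Those downward were kin1 (-5.20 ± 0.107), amy2 (-4.01 ± 0.0795), hsp82 (-3.83 ± 0.316), TMT (-3.46 ± 0.120) and adh2, an alcohol dehydrogenase gene (-3.00 ± 0.112).

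Genes changed in both mutants were compared against the same WT libraries. r1, hsp82, HSP90-1, plt1 and hsp101 rose in both, and nkd2, hyd3, PDIL5-1 (GRMZM2G443655), HO1 and lrk1 fell in both. plt1 was 144.9 ± 12.7 RPKM in the libraries labelled nkd1-Ds and 140.7 ± 43.7 RPKM in nkd2-Ds. lrk1, a receptor-like kinase gene, was 3.59 ± 0.973 RPKM in WT, 0.00591 ± 0.00682 in the libraries labelled nkd1-Ds and 0.0568 ± 0.0109 in nkd2-Ds. At least a 2-fold change in the same direction in both was found for 696 genes, 338 higher and 358 lower.

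limma called 5084 genes in the same direction in both comparisons, 2232 higher and 2852 lower, which is 74.5% of the nkd2-Ds calls, and 311 in opposite directions (106 higher in the libraries labelled nkd1-Ds and 205 higher in nkd2-Ds). Independent lists of these sizes would share 848 higher and 1058 lower genes. In 100 simulations of unchanged groups against shared controls limma called 0 genes in both, and 383 on average, with a highest count of 2446, at an unadjusted p under 0.05 against 6985 observed. With WT libraries split 2 and 2 between the comparisons, 2949 to 3661 genes were called in both. The correlation of changes across genes, which are not independent replicates, was 0.67, and 0.59 to 0.63 with split controls. Simulated correlations had a mean of 0.49 and a highest value of 0.89, so that unchanged groups against shared controls also reached the observed one. The covariance was 0.198 against a simulated mean of 0.0110 and a simulated highest of 0.0374, a difference of 0.187, and 0.182 to 0.193 with split controls. Because nkd2 transcript was low in both mutant groups, the overlap cannot be read as that of mutants with separate defects.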

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

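The gene list test of the direct comparison and quantile normalization were planned, while their use to weigh an explanation and the other tests of an explanation in this part were chosen after the result they bear on was seen. The first pattern is the low nkd2 transcript in the libraries labelled nkd1-Ds, with a log2 change of -3.29 against WT. A swap of libraries between the mutant groups is argued against by nkd1, whose lowest value in nkd2-Ds was 33.3 RPKM, above the highest of 14.4 RPKM in the libraries labelled nkd1-Ds. A chromosome segment around nkd2 shared by both mutant groups may be involved. Only 12141 of the tested genes could be placed in gene order, so unplaced tested genes near nkd2 are not counted. Of the 50 placed genes around nkd2, with nkd2 itself left out, 4 changed at least 2-fold the same way in both. r1 and hyd3 were among them, and their changes in both mutants had been seen before the window was drawn. Other windows of placed genes had a median of 0 and a highest count of 5, and 2.11% held as many as this window. The count was first made with nkd2 itself, which gave 5, and nkd2 was then left out because it is the pattern itself. Loss of nkd1 transcript lowering nkd2 stays open too and cannot be told apart from a shared segment, since no library has low nkd1 beside an nkd2 region known to be wild type.

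The second pattern is the high level of heat shock genes in the libraries labelled nkd1-Ds. Quantile normalization in place of the authors' scaling left the heat shock median at 1.59, with 11 members higher and 1 lower. It moved the zein median from -0.85 to -0.19, where it evens out the highest values. The median of all genes was -0.02 on the authors' scale and -0.01 with quantile normalization, so that setting could hardly have changed the heat shock median. Total-reads scaling moved the median of all genes to 0.43, and the list stayed higher there. These settings show only that the rise held under the scalings tried. Warmer plants or handling at collection of these 4 libraries and genotype both stay open. Their lowest list mean lay 1.64 log2 units above the highest WT library, and the direct comparison of the mutants had a camera adjusted p of 1.48e-05 (0.257 with an estimated correlation), but either explanation would give both values, so they favour neither. Collection and genotype cannot be told apart, because the labels give no collection date or batch.

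The third pattern is that r1 was on in both mutants while anthocyanin enzyme genes rose in nkd2-Ds and mostly not in the libraries labelled nkd1-Ds. Less aleurone RNA in the latter may contribute. The median difference of 8 aleurone genes between the mutants was 0.81, below the median of 2.205 of 8 anthocyanin enzymes. It cannot show less aleurone RNA in the libraries labelled nkd1-Ds, because it also holds any rise in nkd2-Ds. Against WT, glb1 rose by 2.29 in nkd2-Ds and was -0.24 in the libraries labelled nkd1-Ds (limma adjusted p = 0.377). ole17 rose by 1.02 in nkd2-Ds and fell by 2.39 in the libraries labelled nkd1-Ds. These 8 genes were not tested as a set against WT. The lowest difference among enzymes called higher in nkd2-Ds than in the libraries labelled nkd1-Ds was 0.69, that of a2 (GRMZM6G474234). Against WT a2 did not rise in nkd2-Ds (log2 -0.06, limma adjusted p = 0.598), so it lies outside this pattern and cannot set a limit. The aleurone differences ranged from -0.22 to 3.41, so their median does not settle the question. Lower c1, the partner of r1, stays a candidate explanation for the enzymes higher in nkd2-Ds, as c1 differed by 0.86, but these values rest on 5 to 39 reads per library and no test separated a lower c1 from a loss of the cells that express it. Lower c1 alone would not account for bz1 (GRMZM2G165390), which rose by 1.34 in the libraries labelled nkd1-Ds and whose difference between the mutants was -0.72, and chi1 differed by -0.46.

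Several named genes were called in opposite directions against WT in the mutants. Their direct difference combines both changes, so that its call follows from this choice of genes and adds no evidence of its own. The difference of nkd2-Ds from the libraries labelled nkd1-Ds was 3.41 for ole17, 2.70 for sus2, 2.80 for ICL, 3.65 for bz2, 2.04 for HMT-4, 1.64 for prp2 and 0.86 for c1, all called lower in the libraries labelled nkd1-Ds than in WT and higher in nkd2-Ds on the authors' scale. The lower call was lost with total-reads scaling for bz2 (adjusted p = 0.274), HMT-4 (0.238), prp2 (0.954) and c1 (0.0807), and with voom for bz2 (0.0659). For adh2 it was -3.00, with adh2 higher in the libraries labelled nkd1-Ds and lower in nkd2-Ds.

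Single libraries stood far from the other 3 of their group in 14 of 270 gene groups, where chance gives 13.5, in 2 of 51 list groups, where chance gives 2.55, and in 0 of 12 groups of library measures. In RPKM, BURP4 was 0.475 in WT replicate 1 (0.0430 to 0.113 in the others), GH3 9.80 in WT replicate 3 (1.07 to 1.10) and SnRK2.5 3.40 in nkd1-Ds replicate 3 (4.27 to 4.41). adh2 was 5.82 in WT replicate 2 (4.71 to 4.88) and 35.8 in nkd1-Ds replicate 1 (28.7 to 28.9), and y1 was 14.5 in WT replicate 4 (11.5 to 11.9). z1A1_8 was 22.3 in nkd1-Ds replicate 3 (25.9 to 26.0), wx1 1926 in the same library (2208 to 2225) and a2 (GRMZM6G474234) 4.21 in nkd1-Ds replicate 2 (4.93 to 5.004). nkd2-Ds replicate 1 held zp27 at 39929 (26925 to 28592), zp15 at 37264 (24351 to 25456) and prp2 at 155.8 (231.6 to 242.2). nkd2-Ds replicate 4 held psad1 at 1.51 (0.800 to 0.909) and pcna1 at 2.90 (1.97 to 2.09). As list means of log2(RPKM + 1), the cell cycle list was 2.40 in nkd1-Ds replicate 1 (2.22 to 2.23) and the ER chaperones 6.39 in nkd2-Ds replicate 4 (6.62 to 6.63).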

How the results depend on the processing

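Scaling by total recovered reads and limma voom on recovered reads were chosen after seeing the data, as were the tests of other splits, and the rest was planned. The edgeR fit planned for read counts was not run, because the branch fixed beforehand for normalized values was used. On the recovered reads only limma voom was fitted, and neither edgeR nor DESeq2 was. Counts of called genes stayed within 1.5 times under quantile normalization, no filter, a value of 0.1 before the logarithm, only the 8 samples compared, and voom. With total-reads scaling the count for nkd2-Ds against WT was 4524 against 6823, and the other comparisons gave 18637 and 14144, with 3702 genes called in both. Leaving out each replicate gave 13646 to 14327 genes for nkd1-Ds, 5340 to 6677 for nkd2-Ds, 9684 to 10693 for the direct comparison and 4010 to 5162 in both, and fewer samples lower the power by construction. The count of gene lists called in nkd2-Ds against WT was 5 and ranged from 3 to 6 when replicates were left out, with 3 without WT replicate 1 and 3 without nkd2-Ds replicate 4. It was 4 to 5 in nkd1-Ds and 5 to 7 in the direct comparison. With an estimated correlation 0, 0 and 0 lists were called, and with fry 11, 8 and 13, for nkd1-Ds, nkd2-Ds and the direct comparison. These tests ask different questions of a list.

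With the replicate number as a block, 14282, 6039 and 10365 genes were called, 4560 in both, and 3 lists in nkd2-Ds against WT, where carotenoid and heat shock lists reached an adjusted p of 0.0525. zp27 in nkd2-Ds lost its call. The numbers do not pair the samples: deviations of same-numbered samples correlated at -0.276 to 0.125, 1 of 12 pairs was above 0.1, and the own number was best in 3 of 24 comparisons. In the libraries labelled nkd1-Ds the sign turned for ppdk2 (0.0521 with quantile normalization, 0.0415 with total-reads scaling), pds1 (GRMZM5G815358, 0.10), rbr3 (0.0164) and sut4 (0.19), the last 3 with total-reads scaling. The cause of these was not tested beyond the shift of the median of all genes, 0.43, under total-reads scaling. The call of sut4 was also lost without WT replicate 1 or 2 or nkd1-Ds replicate 4 (adjusted p 0.0568 to 0.0723), and rbr3 in nkd2-Ds was lost without WT replicate 4 (0.0545). bap1a passed without WT replicate 4 in nkd1-Ds (0.00549) and nkd2-Ds (0.00782) and without nkd2-Ds replicate 4 (0.0408), bap1b without nkd2-Ds replicate 1 (0.00121), and d9 in nkd2-Ds without WT replicate 3 (0.0362).

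Of the 35 splits of the 8 samples into 4 and 4, 1 gave as many calls with limma as the real one in each comparison, namely the real one itself. It called 14877, 6823 and 11157 genes against 0 in the highest other split. Every other split mixes the genotypes, so real differences widen its spread and lower its calls. The smallest possible share is 1 of 35, so these splits are too coarse to exclude chance. At an unadjusted p under 0.05 the highest other splits gave 3953, 4096 and 3663 genes. Depth limits genes near the 1 RPKM filter, such as c1, which had 5 to 39 reads per library.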

Other observations

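The genes in this part were chosen after their values were seen. betl9, a gene of the basal transfer layer, the tissue that takes up sugars from the mother plant, was 492.4, 248.6, 287.9 and 93.1 RPKM in WT replicates 1 to 4, 133.1, 128.3, 248.6 and 275.6 RPKM in the libraries labelled nkd1-Ds, and 44.3, 236.7, 213.1 and 660.2 RPKM in nkd2-Ds. mn1, the cell wall invertase gene of this layer, was 33.1, 16.1, 28.9 and 6.08 RPKM in WT, 7.67, 9.35, 17.2 and 27.2 RPKM in the libraries labelled nkd1-Ds, and 1.33, 14.1, 11.01 and 44.3 RPKM in nkd2-Ds. Neither gene passed limma's threshold in any comparison, with adjusted p of 0.662 and 0.709 for nkd1-Ds against WT, 0.800 and 0.556 for nkd2-Ds against WT, and 0.932 and 0.764 for the direct comparison.

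In the gene order of assembly NAM-5.0, the genes besides r1 and hyd3 that changed at least 2-fold the same way in both mutants among the 50 placed genes around nkd2 were GRMZM2G017414, the nearest placed gene on 1 side of nkd2, which rose by 2.07 in the libraries labelled nkd1-Ds and 1.94 in nkd2-Ds, and GRMZM5G843302, which fell by 1.09 and 1.73. Tested genes that could not be placed may lie between. Around nkd1 the window of 50 placed genes held 1 such gene, and 30.8% of windows elsewhere held as many.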
